A study of Brassica napus with 8 samples.

How the data were processed

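Gene expression was measured in seeds of Brassica napus cultivar Libomir on 8 Agilent arrays with 60-mer probes, each hybridised with 2 labelled extracts, 1 in red (Alexa Fluor 647) and 1 in green (Alexa Fluor 555). The 5 seed states were dry unprimed seeds (UPd), seeds soaked in polyethylene glycol at −1.2 MPa for 7 days at 25 °C and not dried (Pnd), soaked and dried seeds (Pd), and unprimed and primed seeds imbibed in water for 7 h (UP7h and P7h). The labels give 4 comparisons with 2 arrays each: soaking (Pnd against UPd), drying (Pd against Pnd), full priming (Pd against UPd) and germination (P7h against UP7h). They state 10 samples, that is 2 replicates of each state; that the arrays of 1 slide shared extracts was not stated. All arrays of replicate 1 lay on slide 1 and all of replicate 2 on slide 2, and each slide was scanned on its own day, so replicate number, slide and scan day could not be separated. The dyes were exchanged between replicates in the drying comparison alone.

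Per the file headers, the spot values are intensity readings of Agilent Feature Extraction 9.1.3.1: mean brightness and median local background in each channel, and processed signals that the software had corrected for background and for dye. The submitters' notes give version 9.1. The deposited LogRatio values are log10 ratios of red over green processed signal, set to 0 where neither channel had a usable signal. The deposited table holds the same log10 ratios, equal to the scanner files within 1e-6 at 100% of the spots. Per the file headers, the other columns used are flags of 0 or 1 (well above background, saturated, outlier), with no ratio or intensity in them. The genome build was not given in the sources used here, the gene names are those of the scanner files, and 0 of the 29992 gene identifiers kept occurred in the gene table supplied with the data. Genes were therefore given by the identifier and description of the array design, without positions.

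From the intensity readings, the background was corrected with the normexp method (offset 50) and each array was normalised by loess within the array, in limma 3.58.1 under R 4.3.3. Control spots (1417 of 45220) were left out, as were spots with an outlier flag, which removed 91 of 43603 probes, and repeated spots of a probe were averaged. Probes were kept when well above background in at least 1 channel on at least 2 of the 8 arrays, which left 32412 probes, of which 7917 had a description that names a function. Saturated spots numbered 0. The share of spots well above background was between 53.6% and 74.1% per channel on slide 1 and between 34.9% and 60.8% on slide 2. The number of arrays limits the precision of every value.

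One limma model was fitted to all 8 arrays, with the 5 states and a dye intercept for each probe, which left 4 residual degrees of freedom. Each comparison is a contrast of 2 states, so soaking, drying and full priming also draw on each other's arrays, which hold these states. P7h and UP7h were on the germination arrays alone, so the other arrays entered that comparison only through the dye term and the pooled spread. The dye term was to be dropped if the drying arrays, with dyes exchanged, correlated positively above 0.3 as red over green, and they correlated at −0.36. A further contrast took the priming effect in imbibed seeds minus that in dry seeds. P-values were two-sided limma moderated tests with Benjamini-Hochberg adjustment over all probes of a comparison, and the threshold was 0.05. Errors are standard errors of this fit. Single arrays are quoted as log2 ratios in the direction of the comparison, with any dye effect still in them. Where a state was well above background in none of its channels, a fold by channel means is also given. For it, dimmer values of that state were raised to the dimmest value well above background in the same channel of that array. It leaves any dye effect in, so it is not a limit on the fitted value.

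Before the data were examined, 24 gene lists, the comparisons, the tests, the alternatives and the rule for named genes were fixed. The lists were LEA proteins and dehydrins, seed storage proteins, oil body proteins, heat shock proteins and chaperones, antioxidant enzymes, cytosolic ribosomal proteins, translation factors, aquaporins, cell wall loosening, gibberellin pathway, abscisic acid pathway, ethylene pathway, proteasome and ubiquitin, tubulins and actins, histones and DNA replication, photosynthesis, lipid mobilisation and glyoxylate cycle, proteases of reserve mobilisation, proline metabolism, lipid transfer proteins, myrosinase and glucosinolate, defence proteins, seed coat markers and endosperm markers. Membership followed the probe descriptions, with the brightest probe of each gene; 1366 genes were in a list and 5 in more than 1. The list of cytosolic ribosomal proteins took in 1 probe described as a mitochondrial protein (TC200172). Each list was tested against the other genes with camera of limma at a preset correlation between genes of 0.01, adjusted over the 96 tests of lists in the 4 comparisons. The tests were repeated with the correlation estimated from the data and with fry.

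The rule for named genes took, among probes past the threshold with a functional name and the same direction on both arrays, the 8 largest rises and the 8 largest falls, and up to 3 past the threshold in each list. Where none passed, it took the 5 smallest p-values. Examples from lists that had no member past the threshold over all probes, and genes that passed over their list alone, were chosen after their values were seen.

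The pipeline was tested on simulated data with the spread of the real arrays and 100 probes changed at each size. Of 4-fold changes it recovered 93% in soaking, 90% in drying, 93% in full priming and 81% in germination. Of 2-fold changes it recovered 59%, 54%, 52% and 12% in the same order. A simulated list that moved was called in each comparison and an unmoved list in none. The simulated noise was independent between probes, so this does not test list calls where genes vary together. The simulated arrays also followed the labels exactly, so the shares recovered hold only where the labels are right. In soaking, the correlation estimated from the data was 0.656 for LEA proteins and dehydrins and −0.088 for proline metabolism.

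The alternatives were no dye term, Agilent's own log ratio, the deposited table, no background correction, median centring in place of loess, Aquantile scaling between arrays, no filter and a stricter filter on brightness (13071 probes), a separate dye intercept for each slide, the slide as a random block, a 2-fold minimum, each array left out in turn, and for lists the estimated correlation, fry and all probes in place of 1 per gene. Leaving out 3 sets of arrays was added after seeing the data. Aquantile scaling left the log ratios of the main fit unchanged, and the deposited table repeats Agilent's own log ratio. Counts of alternatives in which a call was kept include both, though neither is a separate check. Groups of samples were taken from the labels alone. No sample column was left unused.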

Results

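Transcript levels in rapeseed were compared across osmopriming, in which seeds take up water from a polyethylene glycol solution, are dried again and are later imbibed in water. Of the 5 seed states, each comparison set 1 pair against each other on 2 arrays, 1 on each slide. The kept probes numbered 32412, and the share of spots well above background was between 34.9% and 74.1% per channel. Values are log2 ratios ± SE from the limma fit to the 8 arrays, with n = 2 arrays per comparison, and array medians are given for the gene lists called in the 4 comparisons.

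Late embryogenesis abundant (LEA) proteins and dehydrins, which protect dry cells, had different levels in the channels of the seed states. Their mean normalised log2 signal over 37 genes was between 9.05 and 9.89 in the 4 channels labelled UPd and between 8.30 and 8.46 in the 4 labelled Pnd. It was 7.17 and 7.36 in the channels labelled UP7h. The channel labelled Pd on the full priming array of slide 1 had 7.71, against 9.39 to 9.64 in the other 3 labelled Pd. The channel labelled P7h had 9.64 on slide 1 and 8.05 on slide 2. Tubulins and actins, the main cytoskeletal proteins, had a mean of 7.55 and 7.53 in UP7h and between 6.76 and 7.07 in the other 14 channels. Across the 3326 brightest probes, which are not independent replicates, 6 of 16 channels correlated best with another channel of their own state. The P7h channels of the 2 slides correlated at −0.62, and that of slide 1 correlated best with a UPd channel (0.91).

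**Figure D1:**
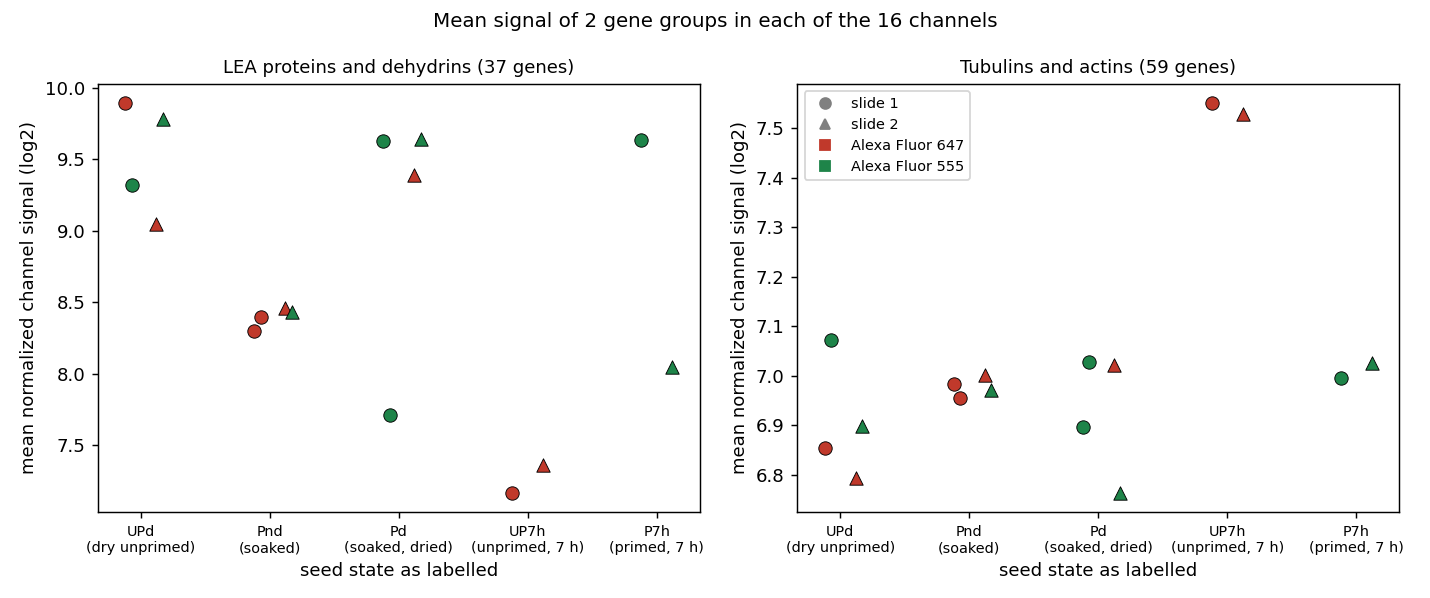
Mean normalised log2 signal of LEA proteins and dehydrins (left, 37 genes) and of tubulins and actins (right, 59 genes) in each of the 16 channels, by the seed state the labels give, with slide as shape and dye as colour. LEA signal was 9.64 in the P7h channel of slide 1 and 8.05 in that of slide 2, and 7.71 in 1 Pd channel against 9.39 to 9.64 in the others.

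Soaking (Pnd against UPd) asked what uptake of water from the osmotic solution does to the dry seed. LEA proteins and dehydrins fell as a group, with a median of −1.48 over 37 genes, 36 of them below 0 (adjusted p = 3.31e-15 by camera; adjusted p = 0.770 with an estimated correlation). Oil body proteins, which coat the seed's lipid stores, fell by a median of 1.04 (adjusted p = 0.0232; adjusted p = 0.770 with an estimated correlation). Genes of myrosinase and glucosinolate, the mustard oil defence of Brassica, fell by a median of 0.52 (adjusted p = 0.0106; adjusted p = 0.772 with an estimated correlation). Proline metabolism rose by a median of 0.32 over 5 genes (adjusted p = 0.0362; adjusted p = 0.770 with an estimated correlation). Translation factors rose by a median of 0.07 (adjusted p = 0.0105) and proteasome and ubiquitin genes, which degrade proteins, by 0.06 (adjusted p = 0.00162). Both had an adjusted p = 0.772 with an estimated correlation.

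Among LEA genes, group 3 LEA (AJ535104) had −2.64 ± 0.94, group I LEA (TA21955_3708) −1.74 ± 0.65 and dehydrin Rab18 (TA21195_3708) −1.32 ± 0.50, and none of them passed alone. An oleosin gene (TA19734_3708), of the structural protein of oil bodies, had −1.10 ± 0.70. Without full priming replicate 1 these genes had −1.70, −1.09, −0.81 and −0.38 in the same order, and without drying replicate 2 group I LEA had −2.91 and the oleosin gene −1.89, which had −1.67 without full priming replicate 2. A delta 1-pyrroline-5-carboxylate synthetase A gene (CX192987), whose enzyme starts proline synthesis, had 0.65 ± 0.15 and was 1 of 2 proline genes that rose, adjusted over the list alone (adjusted p = 0.0256), with 0.39 to 1.58 over the alternatives. Abscisic acid insensitive 5 (TA19548_3708), a transcription factor of abscisic acid signalling in seeds, fell by 0.85 ± 0.15, adjusted over the list alone (adjusted p = 0.0490), with −1.15 to −0.47 over the alternatives. In the same way 2 proteasome genes and 1 protease gene, serine carboxypeptidase-like 7 (CD836436), rose, the last by 0.67 ± 0.11 (adjusted p = 0.0263), with 0.57 to 1.12 over the alternatives. Over all genes tested none of these passed.

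By limma, 0 of 32412 probes passed in soaking. At an unadjusted p under 0.05 there were 2118, against 1621 by chance, and the smallest adjusted p was 0.497. The smallest p-values belonged to Root hair defective 3 (TC191954) at 1.23 ± 0.14, 26S proteasome subunit RPN2a (CD837823) at 0.60 ± 0.07, methionine aminopeptidase 2B (EE458430) at 0.51 ± 0.07, a 26S proteasome regulatory subunit (TA24310_3708) at 0.51 ± 0.07 and glyoxysomal beta-ketoacyl-thiolase (CD824447) at 0.95 ± 0.13, none past the threshold. Over the alternatives CD837823 ranged from 0.39 to 0.81, EE458430 from 0.49 to 0.99 and TA24310_3708 from 0.43 to 0.91. The brightest probe of TA24310_3708, which the lists used, had 0.86 ± 0.11. The array medians of slides 1 and 2 were −0.95 and −1.26 for LEA genes, −0.64 and −0.55 for oil body proteins, −0.09 and −0.32 for myrosinase genes, and 0.19 and 0.68 for proline genes. They were −0.01 and 0.02 for translation factors and −0.02 and 0.03 for proteasome genes. With a separate dye intercept for each slide, the LEA median was −1.56 (adjusted p = 8.63e-16), the 6 called lists stayed past the threshold and 0 probes passed. Without full priming replicate 1 the LEA median was −0.74, that of translation factors 0.03 and that of proteasome genes 0.03, all past the threshold, and the oil body and myrosinase medians of −0.44 and −0.04 were not. Without full priming replicate 2 the myrosinase median was −0.89, and those of translation factors (0.08) and proline genes (0.35) were not past the threshold. Without drying replicate 2 the medians were −1.67 for oil body proteins, 0.19 for translation factors and 0.14 for proteasome genes, and that of proline genes (0.29) was not past the threshold. Proline genes did not pass without soaking replicate 1 (0.45) or soaking replicate 2 (0.20) either. With Agilent's own log ratio the medians were 0.16 for translation factors, 0.16 for proteasome genes, −0.84 for myrosinase genes and 0.67 for proline genes, the last not past the threshold. By fry 0 lists passed. Seed storage proteins had the smallest adjusted p of the lists not called, 0.0769, with a median of −0.75.

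Drying (Pd against Pnd) asked what drying back does to soaked seeds. LEA proteins and dehydrins rose as a group, with a median of 0.89 and 36 of 37 genes above 0 (adjusted p = 1.10e-12; adjusted p = 0.770 with an estimated correlation). Cytosolic ribosomal proteins rose by a median of 0.10, with 266 of 344 genes above 0 (adjusted p = 3.41e-11; adjusted p = 0.772 with an estimated correlation). Proline metabolism fell by a median of 0.39, with 4 of 5 genes below 0 (adjusted p = 0.00349; adjusted p = 0.770 with an estimated correlation). Group 3 LEA (AJ535104) had 1.97 ± 1.02, dehydrin Rab18 (TA21195_3708) 0.89 ± 0.54 and group I LEA (TA21955_3708) 0.84 ± 0.71, none past the threshold alone. Without drying replicate 2 they had 4.21, 2.18 and 3.19, and without drying replicate 1 group I LEA had 0.45. The delta 1-pyrroline-5-carboxylate synthetase A gene CX192987 fell by 0.65 ± 0.17, adjusted over the list alone (adjusted p = 0.0392), and 1 proteasome gene fell by the same test. CX192987 ranged from −2.04 to −0.12 over the alternatives. Over all genes tested neither passed.

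By limma, 0 of 32412 probes passed in drying. At an unadjusted p under 0.05 there were 772, fewer than the 1621 by chance, and the smallest adjusted p was 0.999995. The lack of calls therefore does not show that no transcript changed. The smallest p-values belonged to RPN2a (CD837823) at −0.66 ± 0.08, Root hair defective 3 (TC191954) at −0.98 ± 0.15, 40S ribosomal protein S12-1 (TA21279_3708) at 0.59 ± 0.10, stress-associated protein 6 (TC188378) at 0.70 ± 0.12 and 40S ribosomal protein S28-2 (TA22557_3708) at 0.39 ± 0.07, none past the threshold. Over the alternatives TC191954 ranged from −1.71 to −0.78, TC188378 from 0.45 to 1.42 and TA22557_3708 from 0.37 to 0.75. On the arrays of slides 1 and 2 the medians were 1.14 and 0.93 for LEA genes, 0.04 and 0.09 for ribosomal proteins, and −0.41 and −0.26 for proline genes. With a separate dye intercept for each slide they were 1.05, 0.14 and −0.57, all still past the threshold, and 0 probes passed. Without drying replicate 2, the array with exchanged dyes, the LEA median was 2.18, that of ribosomal proteins −0.14 (adjusted p = 0.00985) and that of proline genes −0.12, the last no longer past the threshold, and without drying replicate 1 that of ribosomal proteins was 0.15. With Agilent's own log ratio ribosomal proteins had 0.33 and proline genes −0.97, both past the threshold. The 2 drying arrays correlated at −0.36 as red over green (0.13 with median centring), while the drying array of slide 1 correlated at 0.90 with the soaking array of slide 2. By fry 0 lists passed. Myrosinase and glucosinolate genes had the smallest adjusted p of the lists not called, 0.0660, with a median of 0.24.

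Full priming (Pd against UPd) asked what soaking and drying leave behind in the dry seed. Genes of the protein machinery rose: cytosolic ribosomal proteins by a median of 0.11 (adjusted p = 1.07e-08; 274 of 344 above 0), translation factors by 0.11 (adjusted p = 3.94e-05; 64 of 83), proteasome and ubiquitin genes by 0.09 (adjusted p = 3.94e-05; 140 of 196) and heat shock proteins and chaperones, which fold proteins, by 0.08 (adjusted p = 0.0264; 59 of 92). With an estimated correlation translation factors had an adjusted p = 0.770 and the other 3 an adjusted p = 0.772. LEA proteins and dehydrins fell in the fit by a median of 0.52 (adjusted p = 0.000502; adjusted p = 0.795 with an estimated correlation). Their arrays went opposite ways, however, with a median of −2.55 on slide 1 and 0.67 on slide 2. The channel labelled Pd on the slide 1 array correlated at 0.86 with P7h of slide 2. With the other Pd channels it correlated at −0.50, −0.60 and −0.79. Whether this channel held dried seeds is therefore in doubt, and with it the reading of the called lists as an effect of priming. Among chaperones, heat shock protein 81-4 (TA20759_3708) had 0.27 ± 0.12 and chaperone protein dnaJ 3 (TA22377_3708) 0.75 ± 0.38, neither past the threshold, and over the alternatives they ranged from 0.17 to 0.59 and from 0.21 to 1.45.

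By limma, 0 of 32412 probes passed in full priming. At an unadjusted p under 0.05 there were 558, fewer than the 1621 by chance, and the smallest adjusted p was 0.895. Here too, the lack of calls does not show that no transcript changed. The smallest p-values belonged to S-adenosylmethionine decarboxylase (TC213385), an enzyme of polyamine synthesis, at −0.29 ± 0.08, 60S acidic ribosomal protein P1-3 (TA21968_3708) at −0.47 ± 0.13, abscisic acid insensitive 5 (TA19548_3708) at −0.54 ± 0.15, lumazine synthase (TC192175) at −0.30 ± 0.09 and branched-chain-amino-acid aminotransferase 2 (CX277965) at −0.30 ± 0.09, none past the threshold. Over the alternatives they ranged from −0.69 to −0.14, −0.91 to −0.26, −0.92 to −0.24, −0.72 to −0.18 and −1.41 to −0.05 in the same order. The array medians of slides 1 and 2 were 0.18 and 0.16 for ribosomal proteins, 0.26 and 0.17 for translation factors, 0.19 and 0.07 for proteasome genes and 0.19 and 0.10 for heat shock proteins. With a separate dye intercept for each slide the 5 called lists stayed past the threshold, with an LEA median of −0.43 (adjusted p = 0.0296), and 0 probes passed. Without full priming replicate 1 the LEA median was 0.33 (adjusted p = 0.0203) and that of proteasome genes 0.02, and without full priming replicate 2 the LEA median was −1.31. Without drying replicate 2 none of the 5 lists passed, with medians of 0.07 for LEA genes, −0.02 for ribosomal proteins, −0.00104 for translation factors, −0.00101 for proteasome genes and 0.01 for heat shock proteins. Heat shock proteins did not pass without full priming replicate 1 (0.03), full priming replicate 2 (0.09) or soaking replicate 1 (0.08) either. With Agilent's own log ratio the medians were 0.41 for ribosomal proteins, 0.37 for translation factors, 0.27 for proteasome genes and 0.32 for heat shock proteins, all past the threshold. The 2 full priming arrays correlated at −0.005 across probes. The full priming ratio correlated with the one given by the soaking and drying arrays of its slide at −0.21 on slide 1 and −0.48 on slide 2. The labels give a positive value on slide 1. On slide 2, where the drying dyes are exchanged, a dye effect alone can make it negative. By fry 0 lists passed. Lipid mobilisation and glyoxylate cycle genes had the smallest adjusted p of the lists not called, 0.0737, with a median of −0.25.

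**Figure D2:**
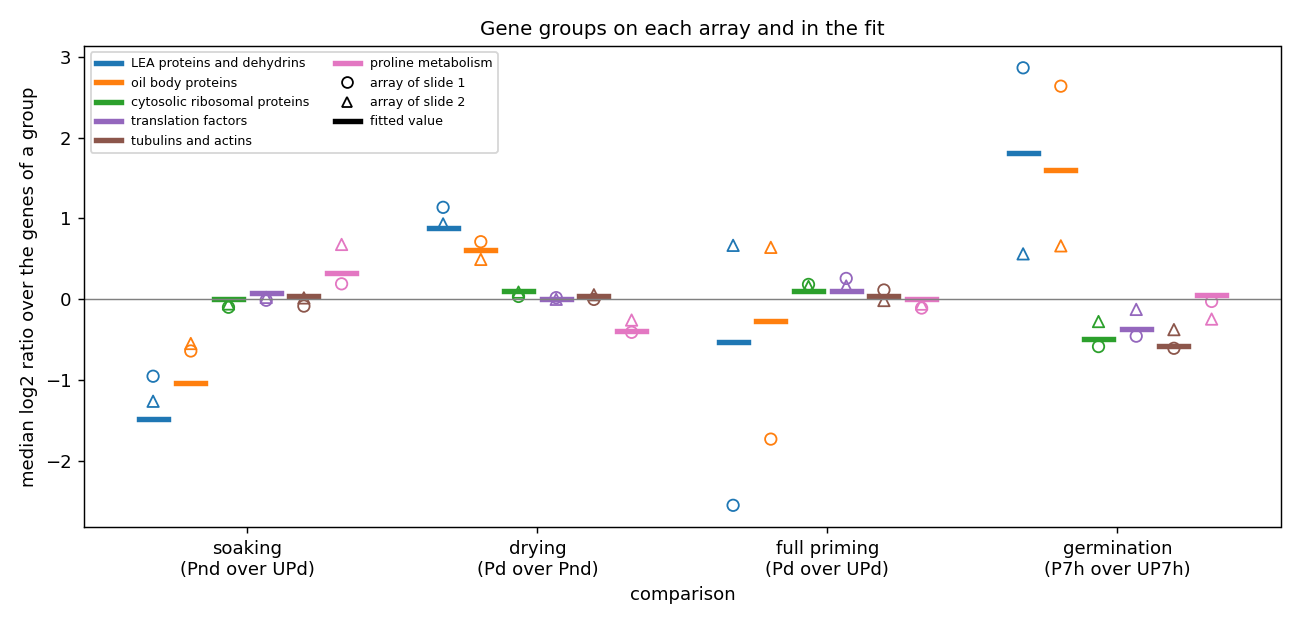
Median log2 ratio of 6 gene groups in each comparison, with bars for the fitted value, circles for the array of slide 1 and triangles for that of slide 2. LEA proteins and dehydrins lay at −2.55 and 0.67 on the full priming arrays and at 2.86 and 0.56 on the germination arrays.

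Germination (P7h against UP7h) asked how primed and unprimed seeds differ after 7 h in water. In seeds labelled primed, the lists of ribosomal proteins, translation factors and tubulins were lower and LEA and oil body genes were higher. Single genes passed too, and 0 of their probes held with a separate dye intercept for each slide. None of these list calls held with an estimated correlation (adjusted p = 0.770 to 0.772 with an estimated correlation) or by fry. An extensin-like gene (TA21761_3708), of a family of structural wall proteins, fell by 4.17 ± 0.37 (17.9-fold; adjusted p = 0.0293), with −6.43 to −3.40 over the alternatives and the call kept in 8 of 20. Xyloglucan endotransglucosylase/hydrolase 19 (TA33890_3708), which cuts and rejoins wall polysaccharides, fell by 2.32 ± 0.20 (adjusted p = 0.0293), with the call kept in 6 of 20. Pectate lyase 5 (TA29011_3708) fell by 2.00 ± 0.26 (adjusted p = 0.0489), though it was well above background in 1 of 2 P7h channels, with −4.52 to −1.54 over the alternatives and the call kept in 3 of 20. Cell wall loosening as a list was not called. A pectinesterase-like gene (CX189843), not well above background in P7h, had a fitted value of −1.61 ± 0.16 and was 3.102-fold lower by channel means.

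A GDSL-motif lipase (TA24372_3708) fell by 2.41 ± 0.15 (adjusted p = 0.0291), with both probes of the gene past the threshold, and with −4.70 to −2.18 over the alternatives and the call kept in 8 of 20. Non-specific lipid-transfer protein 5 (TA20374_3708) had a fitted value of −2.25 ± 0.14 on the 1 of its 2 probes that passed, nitrilase 2 (TA34915_3708) of −2.25 ± 0.20 and a CBL-interacting protein kinase (TA28809_3708), of calcium signalling, of −2.29 ± 0.26. A glycosyl hydrolase of family 17 (TA24983_3708) fell by 2.21 ± 0.26, and a myrosinase-binding protein gene (TC165398) fell by 2.09 ± 0.26, with −4.07 to −1.59 over the alternatives. The calls of these 5 genes were kept in 5 or 6 of 20. Not well above background in P7h were another lipid-transfer protein (TA27838_3708) at −1.45 ± 0.18 and thioglucosidase 3D (DY024129) at −1.90 ± 0.25. The same held for a tonoplast intrinsic protein (CD815565), a water channel of the vacuole, at −1.81 ± 0.20. By channel means these were 2.76-fold, 3.50-fold and 3.29-fold lower in the same order. Their adjusted p-values were between 0.0291 and 0.0489.

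Among the genes that rose was dehydration-responsive element-binding protein 2B (TC199148), a transcription factor of the drought response, at 2.04 ± 0.23 (adjusted p = 0.0422). A glutathione transferase (TC211412), of a family of detoxifying enzymes, rose by 2.02 ± 0.14 (adjusted p = 0.0291). Smaller rises were those of a membrane related protein (TA32901_3708) by 1.47 ± 0.13, with all 3 probes past the threshold, PCF11 (AJ271780), of a family acting in mRNA cleavage, by 1.40 ± 0.17, with 1.09 to 3.09 over the alternatives, and a gene described as TIP (TC197165) by 0.90 ± 0.11. The calls of these 5 genes were kept in 4 to 6 of 21 alternatives.

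**Figure D3:**
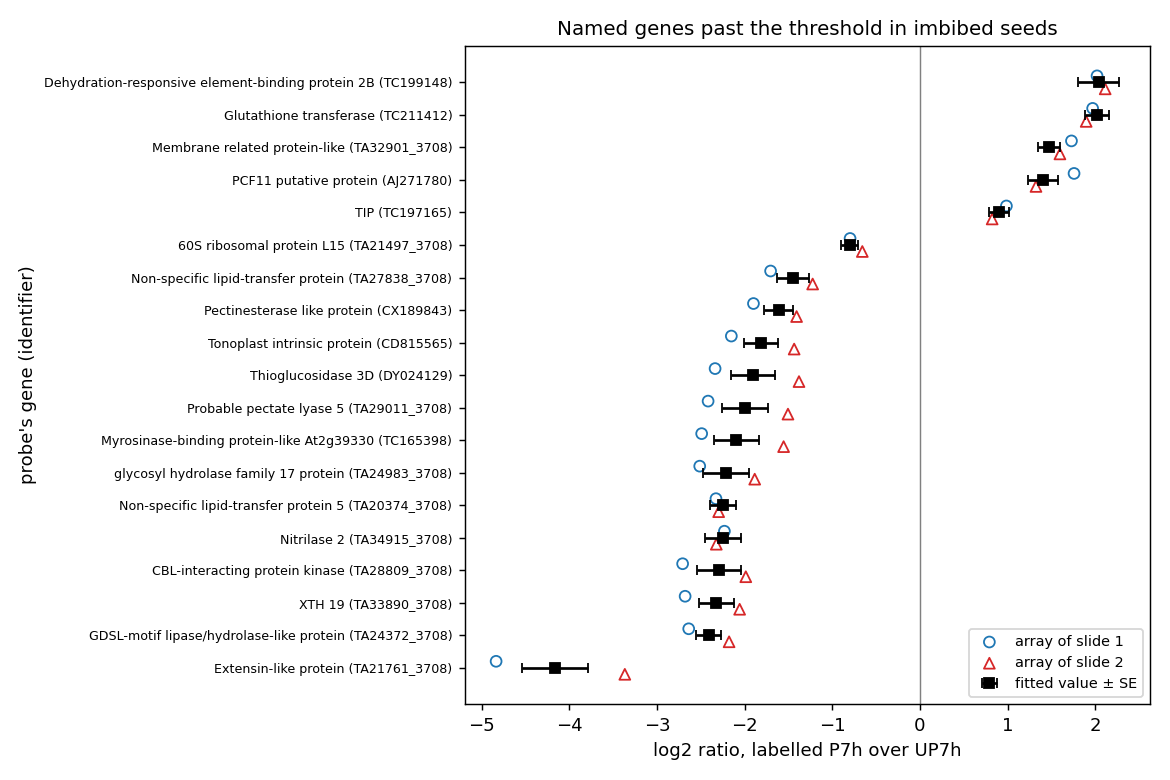
Log2 ratio of labelled P7h over UP7h for 19 named genes past the threshold, with squares and bars for the fitted value ± SE, circles for the array of slide 1 and triangles for that of slide 2. The extensin-like gene lay lowest at −4.17 and dehydration-responsive element-binding protein 2B highest at 2.04.

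Gene groups moved as well. Cytosolic ribosomal proteins fell by a median of 0.49, with 308 of 344 genes below 0 (adjusted p = 7.83e-22; adjusted p = 0.770 with an estimated correlation), and 104 of them passed when adjusted over the list alone against 1 over all genes tested. That 1 was 60S ribosomal protein L15 (TA21497_3708), which fell by 0.80 ± 0.10 (adjusted p = 0.0437). Tubulins and actins fell by a median of 0.57, with 49 of 59 genes below 0 (adjusted p = 1.68e-08; adjusted p = 0.770 with an estimated correlation). Adjusted over the list alone, 20 of them fell, such as tubulin alpha-2 (AY373426) by 1.94 ± 0.55 and tubulin alpha-3/alpha-5 (TA25395_3708) by 1.52 ± 0.28, the last with −1.95 to −1.004 over the alternatives. Translation factors fell by a median of 0.37 (adjusted p = 8.28e-06; adjusted p = 0.770 with an estimated correlation), and elongation factor 1-alpha (TA20530_3708) fell by 1.09 ± 0.16, adjusted over the list alone (adjusted p = 0.0361).

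LEA proteins and dehydrins rose by a median of 1.81, with 37 of 37 genes above 0 (adjusted p = 3.69e-07; adjusted p = 0.772 with an estimated correlation). Oil body proteins rose by a median of 1.59, with 9 of 10 genes above 0 (adjusted p = 0.04997, just past the threshold; adjusted p = 0.772 with an estimated correlation). Group 3 LEA (AJ535104) had 2.79 ± 1.32, group I LEA (TA21955_3708) 2.65 ± 0.92, dehydrin Rab18 (TA21195_3708) 1.48 ± 0.70 and the oleosin gene (TA19734_3708) 2.06 ± 0.99, none past the threshold alone. On the array of slide 1 they had 3.93, 3.18, 1.94 and 3.04, and on that of slide 2 1.60, 1.39, 0.79 and 1.30. Over the alternatives they ranged from 0.99 to 4.19, 1.32 to 4.11, 0.56 to 2.29 and 0.71 to 3.05. Seed coat markers, such as enzymes of flavonoid synthesis, rose by a median of 0.33 (adjusted p = 0.0345; adjusted p = 0.770 with an estimated correlation), and photosynthesis genes by 0.16 (adjusted p = 0.0386; adjusted p = 0.775 with an estimated correlation). The photosynthesis median turned to −0.08 with the stricter filter, and its call held in 11 of 24 alternatives. Of the seed coat markers 2 rose when adjusted over the list alone, 1 of them a leucoanthocyanidin dioxygenase-like gene (CD814698) by 0.74 ± 0.18, with 0.42 to 0.91 over the alternatives.

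By limma, 189 of 32412 probes passed in germination, from 175 genes, of which 25 rose and 164 fell, all of them in the same direction on both arrays. The calls were made from these 2 arrays, both with P7h in green, so this shared direction is not separate support. At least 2-fold were 160 of the 189, and at an unadjusted p under 0.05 there were 6116. With a separate dye intercept for each slide 0 probes passed (smallest adjusted p 0.0948), and median centring, the stricter filter and leaving out any 1 of 7 arrays also gave 0, while without germination replicate 2 there were 804 and without a dye term 1098. Agilent's own log ratio gave 47 probes, no background correction 110 and the slide as a random block 111. The probes that fell had array medians of −1.50 and −1.17 on slides 1 and 2, and those that rose 1.35 and 1.27.

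The array medians of slides 1 and 2 were 2.86 and 0.56 for LEA genes, 2.64 and 0.66 for oil body proteins, −0.58 and −0.27 for ribosomal proteins, −0.45 and −0.12 for translation factors, −0.60 and −0.37 for tubulins and actins, 0.30 and 0.09 for seed coat markers and 0.18 and −0.02 for photosynthesis genes. Blocked by slide, the LEA median was 1.85 (adjusted p = 5.14e-07), that of ribosomal proteins −0.47, of tubulins and actins −0.60 and of translation factors −0.36, and the oil body list no longer passed (adjusted p = 0.0501). Without germination replicate 1 the LEA median was 0.67 and that of translation factors −0.14, both past the threshold, and those of oil body proteins (0.70), photosynthesis genes (0.03) and seed coat markers (0.20) were not. Without germination replicate 2 the LEA median was 2.77, that of oil body proteins 2.65, that of photosynthesis genes 0.27 and that of translation factors −0.58. Photosynthesis genes did not pass without soaking replicate 1 (0.14), full priming replicate 1 (0.18) or drying replicate 2 (0.20), nor oil body proteins without soaking replicate 1 (1.62), nor seed coat markers without drying replicate 2 (0.36). Without full priming replicate 1 and germination replicate 1 together the LEA median was 0.38, that of ribosomal proteins −0.34 and that of translation factors −0.13, all past the threshold, and those of oil body proteins (0.31), photosynthesis genes (0.06) and seed coat markers (0.23) were not. With Agilent's own log ratio the 7 lists passed, with −0.79 for ribosomal proteins, −0.62 for translation factors, 2.47 for oil body proteins, 0.75 for photosynthesis genes and 0.89 for seed coat markers. The LEA signal of the P7h channel on slide 1 was 9.64, within the range of the UPd channels. By fry 0 lists passed.

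Lists not called in germination included seed storage proteins, whose median was 1.40 (adjusted p = 0.0599), with arrays at 2.41 and −0.11. Genes of the abscisic acid pathway, the hormone of seed dormancy, had a median of 0.13 (adjusted p = 0.0643), histones and DNA replication −0.09 (adjusted p = 0.0830), cell wall loosening −0.06 (adjusted p = 0.0919) and proteases of reserve mobilisation −0.04 (adjusted p = 0.321). Heat shock proteins and chaperones had −0.03 (adjusted p = 0.370), myrosinase and glucosinolate genes 0.42 (adjusted p = 0.698), endosperm markers −0.07 (adjusted p = 0.701), proteasome and ubiquitin −0.05 (adjusted p = 0.725) and defence proteins 0.10 (adjusted p = 0.758). Lipid mobilisation and glyoxylate cycle genes had 0.13 (adjusted p = 0.831) and antioxidant enzymes 0.02 (adjusted p = 0.866). Gibberellin pathway genes had 0.17 and ethylene pathway genes 0.14 (both adjusted p = 0.985). Proline metabolism (0.05; adjusted p = 0.831), lipid transfer proteins (0.05; adjusted p = 0.971) and aquaporins (0.13; adjusted p = 0.985) had a median above 0 while the test pointed down. None of the lists that were fixed as markers of the seed coat or the endosperm passed in the other comparisons.

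The priming effect in imbibed seeds was also set against that in dry seeds. LEA proteins and dehydrins had a more positive effect in imbibed seeds, with a median difference of 2.40 (adjusted p = 8.28e-08; adjusted p = 0.734 with an estimated correlation). The same held for oil body proteins at 1.89 (adjusted p = 0.0246; adjusted p = 0.690 with an estimated correlation), seed storage proteins at 1.76 (adjusted p = 0.0246; adjusted p = 0.734 with an estimated correlation) and photosynthesis genes at 0.19 (adjusted p = 0.0221; adjusted p = 0.757 with an estimated correlation). The effect was more negative in imbibed seeds for cytosolic ribosomal proteins at −0.60 (adjusted p = 2.65e-22), translation factors at −0.49 (adjusted p = 4.92e-07) and tubulins and actins at −0.61 (adjusted p = 2.90e-07), all 3 with an adjusted p = 0.630 with an estimated correlation. Adjusted over the list alone, 153 of 344 ribosomal proteins and 22 of 59 tubulins and actins passed, all downward.

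By limma, 0 of 32412 probes passed in this contrast, with 7730 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0588. That value was shared by a GDSL-motif lipase (TA24372_3708) at −2.42 ± 0.17, non-specific lipid-transfer protein 5 (TA20374_3708) at −2.27 ± 0.16, a glutathione transferase (TC211412) at 1.82 ± 0.15, protein disulfide-isomerase 1 (TA22114_3708), an enzyme of protein folding, at −1.73 ± 0.15 and calreticulin (TC185449), a calcium-binding chaperone, at −1.98 ± 0.17. None of them passed, and over the alternatives TA24372_3708 ranged from −4.58 to −2.19 and TC185449 from −3.70 to −1.72. Blocked by slide, the 7 called lists stayed past the threshold, with an LEA median of 2.37, and 0 probes passed. Without germination replicate 2, 1758 probes passed, and the medians were 2.87 for seed storage proteins, 2.95 for oil body proteins and 0.35 for photosynthesis genes. Without full priming replicate 1 the LEA median was 1.06, and seed storage (1.29), oil body (0.80) and photosynthesis (0.24) lists did not pass. Without germination replicate 1 it was 1.12, that of translation factors was −0.29, and the same 3 lists did not pass (0.66, 0.90 and 0.06). Without both of these arrays the LEA (0.25; adjusted p = 0.504), seed storage (0.59), oil body (0.14) and photosynthesis (0.05) lists did not pass, and the ribosomal (−0.43), translation factor (−0.24) and tubulin (−0.42) lists did. With Agilent's own log ratio the 7 lists passed, with 3.34 for seed storage proteins, −1.17 for ribosomal proteins, −1.02 for translation factors, −0.92 for tubulins and actins and 0.81 for photosynthesis genes. By fry 0 lists passed.

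No probe passed both in soaking and in full priming, or both in full priming and in germination. With 0 probes past the threshold by limma in soaking and in full priming under every setting, against 2118 and 558 at an unadjusted p under 0.05, an overlap could not have been found, so this count tests nothing.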

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

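All tests of the correlation patterns in this part, dye effects and sums over a slide included, were chosen after the results were seen, as were the fits without sets of arrays, while the contrast between imbibed and dry seeds was planned. The pattern of slide 1 ratios that do not add up was chosen after both of its sums were seen. It took the place of the partial likeness of the germination arrays, which correlated at 0.4486 and whose explanation by an exchange of green extracts the sum could not test.

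A camera test of the difference itself called 7 gene lists with another priming effect in imbibed than in dry seeds. None of the 7 calls held with an estimated correlation (smallest adjusted p = 0.630 with an estimated correlation) or by fry. The median log2 differences were 2.40 for LEA proteins and dehydrins, 1.76 for seed storage proteins, 1.89 for oil body proteins, −0.60 for cytosolic ribosomal proteins, −0.49 for translation factors, −0.61 for tubulins and actins and 0.19 for photosynthesis genes. Without full priming 1 and germination 1 the 4 upward lists did not pass, with 0.25 for LEA proteins (adjusted p = 0.504), 0.59 for seed storage proteins, 0.14 for oil body proteins and 0.05 for photosynthesis genes, while the 3 downward lists did. E1A control spots, which detect RNA added in the laboratory and enter no comparison, were well above background in 36.9% to 83.8% of 320 spots per channel, against at most 2.61% of 153 negative control spots. The highest share was in the red channel of full priming 2, whose green channel had 39.4%; no explanation was tested for this.

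The drying array of slide 1 and the soaking array of slide 2 correlated at 0.90 across probes. Both have Pnd in red, and a shared state by itself gives a correlation of 0.50 where the states differ independently and by the same spread. A dye effect stays open as a part of the likeness, since the correlations of these arrays with the germination arrays, which share no state with them, had a median of 0.2031. Dried primed seeds that resemble unprimed dry seeds stay open too, though soaking 1 and drying 1 correlated at only 0.4155. LEA levels in 3 of 4 Pd channels lay within the range of UPd, and Pd of full priming 2 correlated at 0.85 with UPd of soaking 2. Pd of drying 1 correlated at 0.91 with UPd of full priming 1, but an exchange of the names of soaking 1 and drying 1 would give this too. Resemblance alone would not set the channel labelled UPd on soaking 1 apart from the other UPd channels. It correlated with them at −0.16, 0.04 and −0.16, against 0.22 to 0.78 among the others. The exchange of names may also account for the likeness of drying 1 and soaking 2, as a hypothesis. It predicts that soaking 1 runs against drying 2 more than drying 1 does, and the difference of these correlations was −0.2245.

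The full priming and germination arrays of slide 1 ran opposite to each other, at −0.6855, which a dye effect shared by all arrays cannot give. A priming effect of opposite sign in dry and imbibed seeds would also make the slide 2 pair negative. That pair correlated at 0.2006, which does not settle the matter. Both arrays have the primed seeds in green, so a dye effect shared by them would raise this correlation. The labels of slide 2 could not be cleared of doubt either. The channel labelled Pd on full priming 1 correlated at −0.50, −0.60 and −0.79 with the other Pd channels, which correlated at 0.30, 0.46 and 0.76 with each other. As labelled, these values argue against a priming effect as the account of the slide 1 pair. An exchange of the green extracts of these arrays predicts that the channel labelled Pd on full priming 1 resembles P7h of slide 2, and it did, at 0.8592, against −0.62 for the channel labelled P7h on germination 1. Such an exchange could explain both the LEA signal of 7.71 in 1 Pd channel and that of 9.64 in the P7h channel of slide 1. A difference between the seed lots of the replicates was not tested. Taken alone, it would leave the 2 Pd channels of replicate 1 alike. As labelled, these had LEA signals of 7.71 on full priming 1 and 9.63 on drying 1 and correlated at −0.50. These values argue against it for Pd, as far as the label of drying 1 holds, and for P7h it stays open.

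The ratios of slide 1 did not add up as labelled, the correlation of full priming with the ratio given by drying and soaking being −0.21. The sum of slide 1 ratios that gives the germination comparison if the names of soaking 1 and drying 1 are exchanged correlated with germination 2 at 0.847, and the sum that gives it as labelled at 0.37. An exchange of these names may account for the pattern, as a hypothesis that these sums prompted and so cannot support on their own. Both sums are the same with or without an exchange of the green extracts, so they do not test that exchange. No biological explanation was tested for this pattern.

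Slide 2 could not be cleared of doubt. The full priming ratio correlated with the one given by soaking and drying at −0.21 on slide 1 (−0.34 to −0.21 over the scalings run). On slide 2 this was −0.48 (−0.48 to −0.26). On slide 1 the dye effect of a probe cancels between drying and soaking, so the labels give a positive value. On slide 2, where the drying dyes are exchanged, it adds up and enters with the opposite sign to that in full priming. A dye effect alone can therefore make the slide 2 value negative, and −0.48 does not tell it from wrong labels. No explanation was tested for slide 2. No call was made from exchanged labels, and every comparison rests on the labels as given.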

How the results depend on the processing

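The fits without sets of arrays were chosen after the data were seen, and the other alternatives were planned.

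Of 1446 values of named genes under the alternatives, 1144 kept their direction and side of the threshold, 283 lost the threshold, 19 gained it and 0 turned. Most of these genes did not pass in the main fit and so had no call to lose. The calls of the 19 germination genes that did pass were kept in only 3 to 8 of 20 or 21 alternatives each. Of 669 list medians 534 kept direction and side of the threshold, 122 lost the threshold and 13 turned. The cause was not tested for any of the changes given here. Signal over background is a limit on slide 2, where 34.9% to 60.8% of spots per channel were well above background, against 53.6% to 74.1% on slide 1.

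Probes passing in germination (189) were 1098 without a dye term, 47 with Agilent's own log ratio or the deposited table, 110 without background correction, 111 with the replicate block as a random effect, and 0 with median centring, the strict filter, or the replicate block as separate dye intercepts. They were 0 to 804 with each array left out, 1 without full priming 1 and germination 1, 0 without both full priming arrays and 0 without soaking 1 and drying 1. Of the 189, 187 were among the 1098, 17 among the 47, 107 among the 110, 111 among the 111 and 162 among the 804. For the difference between stages, 13 passed with Agilent's own log ratio or the deposited table and 0 to 1758 with each array left out. In soaking, drying and full priming 0 probes passed by limma under every alternative run.

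The replicate number is also the slide, and the labels do not say that it marks shared material. Deviations of the 2 replicates from their mean correlated at 0.62 between soaking and drying and between −0.52 and −0.24 for the other 5 pairs of comparisons, and the consensus correlation within a slide was −0.08. With the replicate block as separate dye intercepts 0 probes passed in any comparison, and 6, 4, 6, 6 and 8 lists in soaking, drying, full priming, germination and the difference, against 6, 3, 5, 7 and 7 without it.

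Lists passing in soaking (6) were 4 without a dye term, only 2 of them among the 6, and 3 without a filter. They were 3 without both full priming arrays, 2 of them among the 6. With the estimated correlation they were 0, with fry 0, and 4 to 8 with each array left out. In drying (3) they were 5 without a dye term, 5 with median centring, 5 without full priming 1 and germination 1, 5 without both full priming arrays, 0 with the estimated correlation and 0 with fry, and 3 to 6. In full priming (5) they were 1 without both full priming arrays, which was not among the 5, 0 with the estimated correlation and 0 with fry, and 0 to 8. In germination (7) they were 4 without a filter, 4 with the strict filter, 0 with the estimated correlation and 0 with fry, and 4 to 9. For the difference (7) they were 4 without a filter, 0 with the estimated correlation and 0 with fry, and 4 to 11.

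These medians turned. In soaking, proteasome and ubiquitin had −0.000335 without a dye term. In drying, cytosolic ribosomal proteins had −0.135 without drying replicate 2 (up to 0.149 with each array left out and 0.327 with Agilent's own log ratio). In full priming, LEA proteins and dehydrins had 0.335 without full priming replicate 1 and without full priming 1 and germination 1, and 0.0732 without drying replicate 2 and without both full priming arrays (down to −1.31 with each array left out). Under the last 2 settings cytosolic ribosomal proteins had −0.0236, translation factors −0.00104 and proteasome and ubiquitin −0.00101 (up to 0.137, 0.1298 and 0.108 with each array left out, and 0.413, 0.370 and 0.274 with Agilent's own log ratio). In germination, photosynthesis had −0.0847 with the strict filter. Median centring moved the median of all probes in the difference to −0.114, and no other setting moved one by over 0.1, fits without arrays included.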

Other observations

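The tests of single genes over a list alone were planned, but the genes below were chosen for naming after their values were seen. Their values come from the germination comparison. Its P7h channel on slide 1 correlated at 0.91 with a UPd channel and at −0.62 with P7h of slide 2. A contrast of dry with imbibed seeds on that array can therefore not be told from an effect of priming.

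In imbibed seeds, 6 of 8 gibberellin pathway genes changed when adjusted over the list alone, 3 up and 3 down, although the list as a whole had an adjusted p of 0.985. Gibberellin is the hormone that promotes germination. DELLA protein RGL3 (TC205772), of a family of repressors of gibberellin responses, fell by 1.09 ± 0.27 (adjusted p = 0.0281 by limma). The gibberellin receptor genes GID1L1 (CB686325) and GID1L3 (TC176449) rose by 1.03 ± 0.24 and 0.78 ± 0.22 (adjusted p = 0.0281 and 0.0316), the last with 0.48 to 1.09 over the alternatives. On the arrays of slides 1 and 2, RGL3 had −1.27 and −0.86, GID1L1 1.26 and 0.60, and GID1L3 0.93 and 0.33. The others of the 6 were gibberellin 2-beta-dioxygenase 2 (TA35819_3708) at 0.67 ± 0.23 and 2 genes of gibberellin-regulated protein 1. These (TA22916_3708 and TA22915_3708) had −0.53 ± 0.16 and −0.47 ± 0.16. A direction of the pathway as a whole cannot be read from these genes. Over all genes tested none of the 8 passed.

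Of 48 ethylene pathway genes, 8 fell in imbibed seeds when adjusted over the list alone and 0 rose, although 28 of the 48 lay above 0 and the list as a whole had a median of 0.14 (adjusted p = 0.985). Among the 8 were genes described only by likeness to ACC oxidase, the enzyme that makes ethylene. An ACC oxidase-like gene (DY023751) had −2.52 ± 0.36 and ACC oxidase homolog 1 (TA29017_3708) −2.17 ± 0.36 (both adjusted p = 0.0108). A gene described as ACC oxidase itself (TC175529) had −2.10 ± 0.43 (adjusted p = 0.0254 over the list alone). Of 82 cell wall loosening genes, whose list had an adjusted p of 0.0919, 9 fell by the same test, such as expansin-A9 (TC163596), which loosens walls, by 1.48 ± 0.21 (adjusted p = 0.00819), with −3.75 to −1.09 over the alternatives, and xyloglucan endotransglucosylase/hydrolase 16 (DY020310) by 2.32 ± 0.40 (adjusted p = 0.0154), with −4.51 to −1.50. Of 22 aquaporins, 14 of them above 0, 3 fell, such as the membrane channel NIP5-1 (TC186158) by 0.61 ± 0.10 (adjusted p = 0.00819), with −1.04 to −0.56. Of 8 lipid transfer proteins 1 fell, as did 2 of 21 myrosinase and glucosinolate genes, of which 17 lay above 0 with a median of 0.42 for the list. Over all genes tested, none of the genes named in this paragraph passed, with adjusted p between 0.0562 and 0.104 by limma.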
